A study of Mus musculus with 6 samples.

How the data were processed

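CUT&Tag was measured in 6 libraries of cultured mouse group 2 innate lymphoid cells (ILC2s) from the colon, with 2 libraries in each of 3 groups named Control, FK866 and FK866 plus succinate. CUT&Tag tethers a transposase to an antibody bound on chromatin, so that DNA near the bound protein or mark is cut and sequenced. The antibody target is not given in the sources used here, so a peak stands only for a stretch enriched for that unnamed target. The groups and replicate numbers were taken from the labels. The labels do not say whether the 2 libraries of a group come from separate cultures or animals, so the p values measure only the spread between these samples.

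Per the submitters' processing notes, reads were trimmed with cutadapt 1.9 and aligned to the mouse assembly mm10 with Bowtie2 2.5.0. The authors then called peaks in each library; the peak caller and its settings are not given in the sources used here. The deposited lists have 10 columns in the narrowPeak layout. The deposited score of a peak is 10 times its -log10 p, with decimals dropped, for between 99.88% and 99.98% of the peaks of each list. The deposited fold enrichment is the ratio of a peak's signal to the local background of the same library. The deposited -log10 p and -log10 q (adjusted p) also refer to 1 library at a time. The weakest peak of every list lay just under a p of 0.05, so the lists were made with a loose threshold. Scores, ratios and p values depend on the depth of their library and were compared only within a list. No read counts, coverage tracks or input control entered the calculations, so no difference in signal height between groups was measured.

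Depth was not given as read counts. It was inferred from the steps between the commonest fold values, which give 1 background value per library, as fragments per position. The inference was checked by recomputing each p from a Poisson distribution. At least 99.0% of the peaks whose fold lay on a whole step (tolerance 0.002) had a p within 0.02 of the recomputed -log10 p. Such peaks made up between 27.8% and 44.2% of each list, and the check does not cover the other peaks. The inferred background was 1.85 and 2.14 fragments per position in the Control libraries, 2.11 and 1.60 in the FK866 libraries, and 1.74 and 1.25 in the FK866 plus succinate libraries. It is a relative measure of depth and sets no counting interval.

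Peaks on the 21 chromosomes 1 to 19, X and Y were kept; between 43 and 55 peaks per library on other sequences were left out. Overlapping peaks of the 6 lists were merged into union regions with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15. A region counted as lost when both libraries of the reference group had a peak of at least 1 bp in it and neither library of the treated group did, and as gained in the reverse case. With 2 libraries against 2, presence calls allow no p under 0.05, so each count was set beside the same count for the 2 other ways of splitting the 4 libraries. Library similarity was the base-pair Jaccard index, with a one-sided exact permutation test over the 15 ways of putting 6 libraries into 3 pairs.

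Genes came from a table of the assembly GRCm38.p6, which has the same chromosome coordinates as mm10. The plan was to measure windows of 2 kb around transcript starts, but the gene table gives only the span of each gene, without strand, transcripts, exons or introns. Windows at gene ends were tried first and missed the main peaks of genes such as Ldha, Hif1a and Rora. Each window was therefore placed 2 kb to either side of the gene's lead site, the peak summit with the highest mean -log10 p percentile over all 6 libraries within the gene span and 2 kb around it. The site itself is picked without regard to group. The change of rule was made after the lost and gained region counts and the values of each library at the panel genes with gene-end windows had been seen, and before limma or any gene list test was run. The rule matters for Rora, whose gene-end window was 26.4 points lower in FK866 plus succinate than in Control (adjusted p = 0.260 from limma) while its lead-site window differed by -0.575 points. limma was also tried once on the covered length of union regions, with 0 regions past an adjusted p of 0.05, and was not taken further. Of 21887 protein-coding genes 15855 had a site, and for 13469 of these it lay within 2 kb of an end of the gene. The lead sites of 3863 genes also lay near an end of another gene, so that neighbours can share a window and a value.

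The measured value of a gene was the percentage of its 4-kb window covered by peaks, a measure of peak width and presence and not of signal height. Windows covered in at least 2 of the 6 libraries (15115 genes) were compared with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3, with no scaling between libraries, 1 spread estimated over all 6 libraries, and Benjamini-Hochberg adjustment at 0.05. Adjusted p values of single genes in the text are from limma. Gene lists with at least 5 measured members were tested with camera, from limma, at an inter-gene correlation of 0.01, and again with a correlation estimated from the residuals. Lost and gained windows in each list were compared with Fisher's exact test, two-sided, through scipy 1.17.1. Camera compares a list with all other genes, so a list can lie above the other genes while its own median change is negative. Covered lengths of 200 intervals were checked against bedtools 2.31.1, with 0 differences.

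The limma and camera steps were tested on simulated data for FK866 plus succinate against FK866, with 50 changed genes at each size among 15115 genes. The changed genes were drawn only from windows of intermediate mean coverage, so recovery at thinly or almost fully covered windows was not tested. At 5 points 0 of 50 changed genes were recovered, at 10 points 17, at 20 points 42 and at 30 points 48, with 4 false calls. A list of 23 genes shifted by 5 points was called in 20 of 20 simulations, and 0 of 600 tests of unchanged lists were called. The simulated noise was independent between genes, so these list results do not show how often camera calls lists of correlated genes. The other 2 comparisons were not simulated.

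The 30 gene lists, a panel of 24 genes, the tests, the alternatives and the rule for naming genes were set before the data were examined. The rule named up to 8 genes per direction among lost or gained windows, ordered by the mean -log10 p percentile of the peak in the 2 libraries that have it. It also took up to 4 lost or gained members per list, all panel genes and up to 3 regions per direction by width, and passed over genes without a name of their own. Genes past limma's threshold would have been named as well, and there were 0. A few genes that the rule or the lists include are not reported here by name. Genes named outside this rule were chosen after their values were seen; they are those past the threshold over their list alone, those picked out of the lists of the closing section and the single genes marked so in the text. The interferon-stimulated, class I antigen presentation and ribosomal protein lists were also written after the window tests were seen.

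The alternatives were another overlap for presence, lists of equal length, the higher-scoring 50% of each list, merging of peaks within 500 bp, windows within 1 kb of the site, quantile normalization, an arcsine square root scale, no filter on coverage, the replicate number as a block, and leaving out each library in turn. Peaks with an adjusted p under 0.05 and windows at gene ends only were added after the data were seen. Figures were drawn with matplotlib 3.10.9. Signal height, transcript starts and exon or intron positions were not analysed here.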

Results

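Group 2 innate lymphoid cells are tissue lymphocytes without antigen receptors that secrete type 2 cytokines such as IL-5 and IL-13. Cells from the mouse gut were kept in culture with the growth cytokines IL-2 and IL-7 and the activating cytokines IL-25 and IL-33, and were left untreated (Control), treated with FK866, an inhibitor of the NAD salvage enzyme NAMPT, or treated with FK866 plus succinate, an intermediate of the tricarboxylic acid (TCA) cycle. Sorted cells were profiled by CUT&Tag, with 2 libraries per group and 6 in all. The peak lists held 50489 and 41023 peaks in the Control libraries, 40320 and 43468 in the FK866 libraries, and 45446 and 56361 in the FK866 plus succinate libraries. The group means were 45756 ± 6693, 41894 ± 2226 and 50904 ± 7718 peaks (SD, n = 2). Peaks with an adjusted p under 0.05 numbered 27735 ± 756 in Control, 27562 ± 976 in FK866 and 26020 ± 1178 in FK866 plus succinate. The lists covered between 39.0 and 43.8 Mb of mm10 per library. The inferred background, the only measure of depth in the lists, lay between 1.25 and 2.14 fragments per position and was lowest in the second FK866 plus succinate library, which also had the most peaks and the smallest median width (528 bp).

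**Figure D1:**
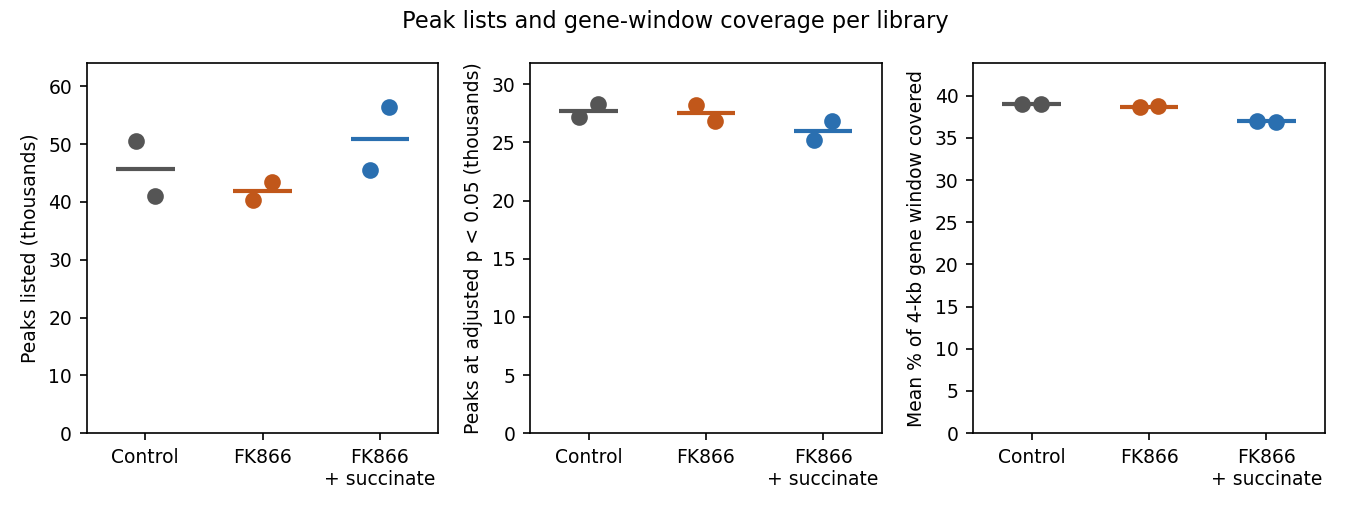
Number of peaks per library (left), number of peaks with an adjusted p under 0.05 (middle) and mean percentage of the 4-kb gene windows covered by peaks (right, 15115 tested windows); dots are libraries and lines are group means (n = 2). Mean coverage was 37.1% and 36.9% in the FK866 plus succinate libraries and between 38.7% and 39.1% in the other 4.

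The 6 lists merged into 101435 regions, of which 22049 (21.7%) had a peak in all 6 libraries and 50163 (49.5%) in 1 library only. A mean of 32.9% of peaks lay within 2 kb of an end of a protein-coding gene, 42.0% elsewhere inside a gene and 25.2% outside genes. Among the 10000 strongest peaks of each list the share near a gene end was 84.0%. On average, libraries of the same group shared slightly more of their covered bases than libraries of different groups, with mean Jaccard indices of 0.572 and 0.563. The exact permutation test over 15 pairings gave a p of 0.133 for this difference of 0.00886, and the smallest p it allows is 0.0667. The same exact test gave that smallest p with lists of equal length (a difference of 0.0102) and, chosen after the results were seen, with peaks at an adjusted p under 0.05 (0.0149), and a p of 0.133 with the higher-scoring 50% of each list (0.0130). Single pairs of the full lists did not all follow the averages. The Control pair shared 0.585, the FK866 pair 0.613 and the FK866 plus succinate pair 0.518. The first FK866 plus succinate library shared more than that, between 0.546 and 0.589, with each Control and FK866 library. The highest index, 0.634, was that of Control 2 and FK866 1.

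Windows at the genes that define ILC2s were broadly covered in all 6 libraries. A peak in all 6 is not particular to these genes, since windows were placed at lead sites over all libraries. Of all genes with a site, 86.1% had a peak in all 6. At Il5 (chr11:53720794-53725103) peaks covered 82.9% ± 3.61 of the window in Control, 87.2% ± 0.0530 in FK866 and 82.1% ± 4.56 in FK866 plus succinate (SD, n = 2 throughout). At Il13 (chr11:53631323-53634702) the values were 57.4% ± 3.59, 74.2% ± 2.95 and 67.0% ± 10.3. Gata3, the transcription factor required for ILC2s, had 59.6% ± 3.64, 57.7% ± 4.30 and 60.5% ± 0.689, and Rora, another regulator of ILC2 development, 65.7% ± 0.902, 65.3% ± 1.59 and 65.2% ± 0.0884. The IL-33 receptor gene Il1rl1 had 81.7% ± 0.0707, 80.6% ± 0.0177 and 80.9% ± 0.336. At Il17rb, which encodes the receptor for IL-25, coverage was 67.4% ± 3.78 in Control, 58.0% ± 4.40 in FK866 and 70.5% ± 3.98 in FK866 plus succinate. The ILC1 regulator Tbx21 (26.1%, 27.0% and 28.8%) was covered less, but Eomes of the ILC1 and NK markers, added after its values were seen, had 60.7% in Control, 60.6% in FK866 and 40.5% in FK866 plus succinate. Il9 had a peak only in the second FK866 plus succinate library, and Sucnr1, Ifng and Il17a had none in any of the 6. None of the panel genes passed limma's adjusted threshold in any of the 3 comparisons.

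The comparison of FK866 with Control asks what blocking NAMPT does to the chromatin profile. Several windows covered in both Control libraries were empty in both FK866 libraries. At Tslp, a cytokine of epithelial cells that acts on ILC2s, coverage was 18.4% ± 6.81 in Control and 0% in FK866 (SD, n = 2), with 12.0% ± 4.44 in FK866 plus succinate. Other windows of this kind were Gpx8, an endoplasmic reticulum peroxidase (12.5% ± 1.87 in Control), the potassium channel gene Kcnk18 (16.4% ± 3.34), Cpne8 (13.2% ± 3.27), C2cd4b (10.95% ± 1.34), Phldb2 (10.3% ± 0.742), Agbl1 (10.2% ± 0.460) and Sntg1 (8.51% ± 1.82). Windows empty in Control and covered in FK866 included Cdh20, a cadherin gene (13.0% ± 3.39), the class II histocompatibility gene H2-Aa (10.6% ± 5.43), Tomm20l (9.41% ± 1.96), the adjoining hedgehog signalling genes Evc and Evc2 (a shared 8.43% ± 1.91), Galr1, a galanin receptor gene (8.10% ± 0.424), Slc27a6, a fatty acid transporter gene (8.04% ± 1.82), and Spata20 (8.03% ± 2.19). Among members of the fixed lists, the gained windows were the immediate early gene Egr3 (8.29% ± 2.21) and the cone opsin gene Opn1sw (9.65% ± 0.636), and each also had a peak in 1 of the FK866 plus succinate libraries.

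In total 111 gene windows lost and 33 gained peaks with FK866. The sum of 144 stood against 125 and 127 for the other 2 splits of the same 4 libraries. Across all regions 2072 were lost and 1420 gained, a sum of 3492 against 3298 and 3585 for the other splits. Lists of equal length gave 1527 regions lost and 1509 gained, and 88 windows lost and 52 gained, while the higher-scoring 50% of each list gave 503 regions lost and 151 gained. The widest lost regions were chr16:22239879-22242846, which lies 1706 bp from Tra2b, chr4:140858862-140861717, 13083 bp from Padi1, and chr18:4335605-4338240 inside Map3k8. The widest gained were chr8:105771492-105773830 inside Ranbp10, chr17:55995909-55998146 over Fsd1 and Stap2, and chr9:21553392-21555339 inside Carm1. Without 1 of the 4 libraries the rule is looser by construction, and the counts became 8630 lost and 3003 gained without Control 1, 15976 and 2557 without Control 2, 3877 and 10126 without FK866 1, and 3555 and 7249 without FK866 2. For windows they became 197 lost and 163 gained, 470 and 92, 278 and 158, and 241 and 101 in the same order.

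Coverage of the windows was similar with FK866, with a median difference over all genes of -0.05 points. Limma called 0 of 15115 genes, and 769 (340 wider and 429 narrower) had an unadjusted p under 0.05 against 754 in each of the other splits. Among the fixed lists, 1 gene passed when adjusted over the list alone. It was Nfkb1, which encodes the p105 and p50 subunits of NF-kB, at 77.2% ± 0.106 in Control and 66.8% ± 0.689 in FK866 (SD, n = 2, adjusted p = 0.0407 over the 16 genes of the NF-kB list and 0.837 over all genes). Genes chosen after their values were seen included Mlxipl, a glucose-responsive transcription factor (49.0% ± 0.672 in Control, 31.5% ± 0.495 in FK866 and 31.4% ± 0.495 in FK866 plus succinate, adjusted p = 0.510). They also included Batf3, a transcription factor of dendritic cells and T cells (38.8% ± 1.73, 17.5% ± 0.0180 and 32.9% ± 4.31, adjusted p = 0.837), and the chemokine receptor gene Ccr4 (55.2% ± 2.14, 67.8% ± 1.96 and 62.4% ± 1.01, adjusted p = 0.837).

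None of the 30 lists passed camera's adjusted threshold for FK866 against Control, and 2 had an unadjusted p under 0.05. Developmental regulators were narrower at 14 of 18 genes, with a median change of -3.65 points (p = 0.0260, adjusted p = 0.435, and p = 0.227 with an estimated correlation). T cell markers were wider at 8 of 10 genes, with a median of 0.788 points (p = 0.0290, adjusted p = 0.435, and p = 0.109 with an estimated correlation). Among them Foxp3 and Cd5 were picked out after their values were seen: Foxp3 had 24.1% ± 3.87 in Control and 41.7% ± 3.25 in FK866, and Cd5 had 18.1% ± 3.34 and 27.9% ± 6.21. The ILC2 cytokine list averaged 52.0% ± 1.47 and 50.8% ± 1.58 over the 11 members with any peak (5 of the 10 tested genes higher, adjusted p = 0.920). The ILC2 receptor list averaged 53.4% ± 0.841 and 54.0% ± 0.929 (11 of 20 higher, adjusted p = 0.920). For NAD synthesis and recycling 10 of 20 genes were higher, with means of 38.0% ± 1.05 and 38.0% ± 0.206 (adjusted p = 0.970), and for the TCA cycle 10 of 23 genes were higher (adjusted p = 0.920). Fisher's exact test of lost or gained windows in each list gave no adjusted p below 0.474.

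Adding succinate to FK866 addresses whether the cells' profile differs from that with the inhibitor alone. The gained window with the strongest peaks was Ifi206, an interferon-inducible gene of the p200 family (chr1:173468485-173491318), at 0% in both Control and both FK866 libraries and 33.3% ± 2.55 in FK866 plus succinate (SD, n = 2). Its family is a cluster of closely similar genes, where short reads align less uniquely. The sphingosine-1-phosphate receptor gene S1pr3 went from 0% to 21.5% ± 3.61, the histamine receptor gene Hrh4 from 0% to 21.0% ± 0.601 and the protease inhibitor gene Serpina3g from 0% to 23.3% ± 15.5, with Control at 12.7% ± 4.45, 19.6% ± 12.8 and 8.28% ± 11.7. Upk2 (17.6% ± 1.38), Ttc9b (19.96% ± 1.86), Ccdc27 (16.3% ± 10.3) and Glrp1 (10.5% ± 1.10) were also covered in both FK866 plus succinate libraries and in neither FK866 library, and each had a peak in at least 1 Control library. Among the ILC3 markers the cytokine gene Il17f was gained, at 9.94% ± 0.124, with 16.35% in the first Control library and 0% in the second.

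Windows with peaks in both FK866 libraries and none with added succinate included Zbtb16, which encodes PLZF, a transcription factor of innate lymphoid precursors (chr9:48651797-48836225). It had 19.9% ± 0.389 in Control, 17.3% ± 3.04 in FK866 and 0% in FK866 plus succinate (SD, n = 2). The developmental genes Wnt7a (23.7% ± 4.77 in FK866), Barx2 (23.6% ± 4.01) and Hoxc8 (9.75% ± 3.08) followed the same pattern, as did Gprin1 (23.8% ± 3.24), Zfp385b (18.8% ± 12.5), Tmem178 (17.9% ± 2.62), Kirrel (17.6% ± 2.86) and the synapsin gene Syn3 (12.9% ± 0.283). The T cell receptor component Cd3e had 7.31% ± 1.64 in FK866, 0% in FK866 plus succinate and a peak in 1 of the 2 Control libraries. Its FK866 peaks were weak, with a mean -log10 p percentile of 24.2.

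**Figure D2:**
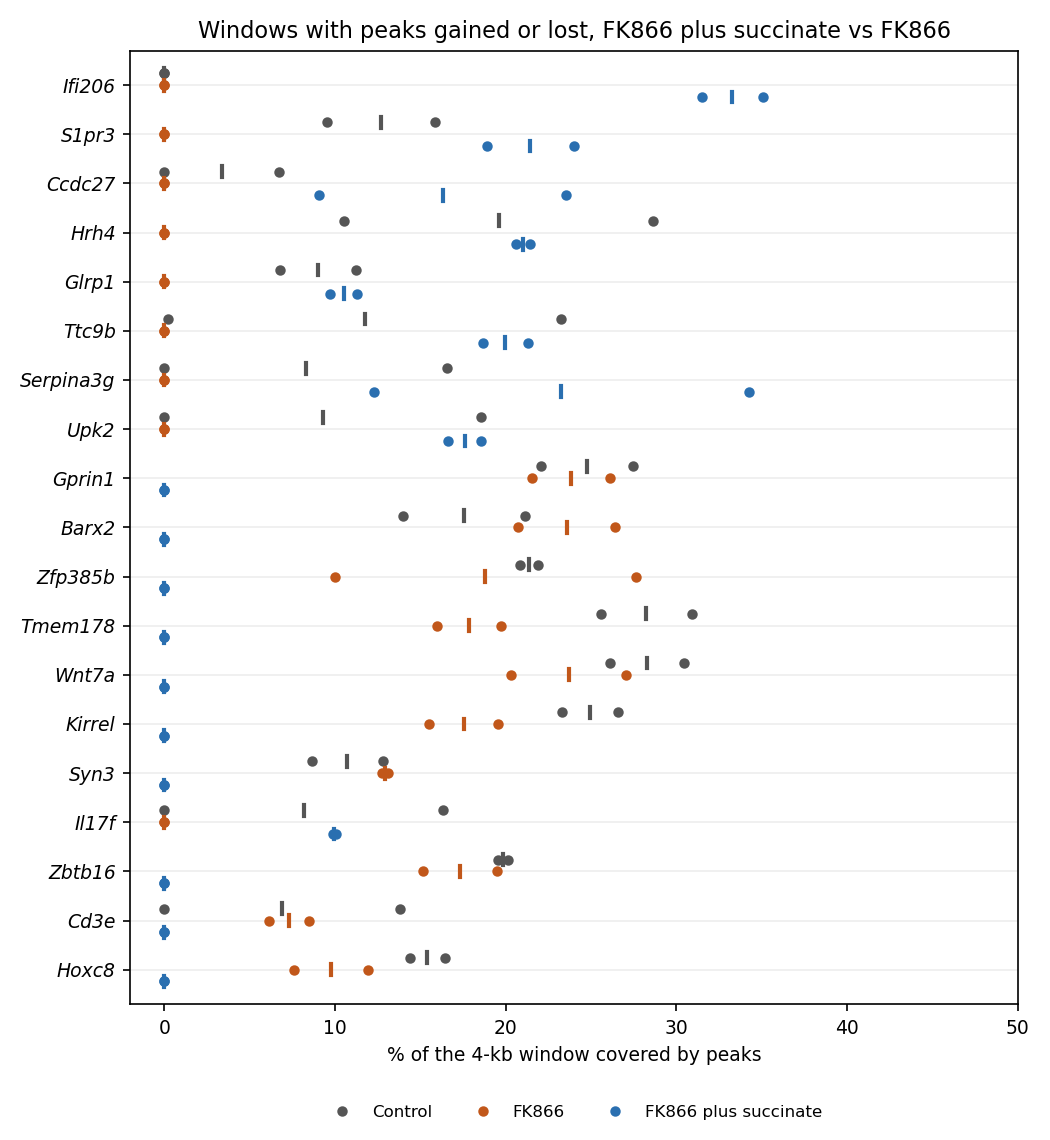
Percentage of the 4-kb window covered by peaks at genes named among windows gained or lost with FK866 plus succinate against FK866; dots are libraries and bars are group means (n = 2). Ifi206 was covered by 31.5% and 35.1% with added succinate and by 0% in the other 4 libraries, and Zbtb16 by 0% with added succinate and between 15.2% and 20.1% in the other 4.

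The gene windows with peaks lost numbered 102 and those gained 129, a sum of 231 against 126 and 115 for the other splits of the 4 libraries. Across all regions 1705 were lost and 2799 gained, a sum of 4504 against 3560 and 3476. The balance of gains and losses depended on the peaks counted: lists of equal length gave 2108 regions lost and 1504 gained, peaks with an adjusted p under 0.05 gave 1257 and 504, and the higher-scoring 50% of each list went the other way with 266 and 1073. The widest gained regions were the same Tra2b and Padi1 regions that were lost with FK866 and chr17:56882205-56884446 inside Acsbg3. The widest lost were chr10:80613825-80616601 inside Scamp4, chr2:24393499-24395746 inside Psd4 and chr14:40935415-40937642 inside Tspan14. With 1 library left out, regions lost and gained became 10242 and 4516 without FK866 1, 7546 and 4374 without FK866 2, 3330 and 22475 without FK866 plus succinate 1, and 3407 and 12700 without FK866 plus succinate 2. For windows the values were 231 and 282, 192 and 258, 221 and 549, and 250 and 275 in the same order.

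Most windows were slightly narrower with added succinate, with a median change over all genes of -1.54 points. Limma called 0 of 15115 genes, with a smallest adjusted p of 0.0777. At an unadjusted p under 0.05 there were 2031 genes, 289 wider and 1742 narrower, against 664 and 544 in the other splits of the 4 libraries. Under quantile normalization the median change was 0.329 points and the unadjusted count was 1533 genes, 711 wider and 822 narrower, so the excess of narrower windows depends on the absence of scaling. Windows within 1 kb of the site gave 28 called genes, all narrower, and peaks with an adjusted p under 0.05 gave 16, of which 2 were wider and 14 narrower, with 0 genes in both sets. Many of the 28 were covered by 100% in both FK866 libraries, which leaves no room to widen and no spread. Galc, for example, had 100% in every Control and FK866 library and 86.25% in both FK866 plus succinate libraries. Neighbours such as Ncor1 and Pigl shared 1 window, so the 28 genes stand for fewer windows. Nampt, which encodes the target of FK866, was among the 28 (a change of -19.9 points, adjusted p = 0.0370). In its 4-kb window it had 53.04% ± 0.0530 in Control, 56.3% ± 4.68 in FK866 and 44.0% ± 0.265 in FK866 plus succinate (SD, n = 2, adjusted p = 0.180). Sdhb, a subunit of succinate dehydrogenase, had 43.1% ± 2.74, 41.7% ± 2.44 and 35.8% ± 0.513, and the glycolytic gene Ldha 61.4% ± 1.70, 63.6% ± 3.36 and 56.5% ± 1.18, with adjusted p values of 0.324 and 0.276.

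Some members of the fixed lists passed when adjusted over the list alone, all of them narrower with added succinate and none past the threshold over all genes. Each list was adjusted on its own, with no further adjustment for the 30 lists. The passing members included Zbtb16 of the ILC2 transcription factors (adjusted p = 0.0281). Another was Eomes of the ILC1 and NK markers, a transcription factor of natural killer cells. It had 60.6% ± 1.06 in FK866 and 40.5% ± 1.06 in FK866 plus succinate (SD, n = 2, adjusted p = 0.00415). Of the 10 measured T cell markers 3 passed, namely Foxp3 (41.7% ± 3.25 and 16.9% ± 13.5), Cd5 (27.9% ± 6.21 and 10.03% ± 1.34) and Cd3d (43.9% ± 3.09 and 33.9% ± 0.283). Of the 29 cell cycle genes 4 passed, namely the replication helicase gene Mcm3 (50.4% ± 1.63 and 36.7% ± 1.34), Ccna2, which encodes cyclin A2 (57.4% ± 0.247 and 49.2% ± 0.672), E2f2 (74.7% ± 5.20 and 59.8% ± 3.82) and Birc5 (56.4% ± 0.849 and 47.5% ± 3.24). The ribosomal protein gene Rpl13a of the housekeeping list (64.3% ± 1.26 and 46.5% ± 1.66), the glycolytic enzyme gene Gpi1 (47.4% ± 1.86 and 31.2% ± 0.283) and Cox7c of the respiratory chain (35.9% ± 0.778 and 27.0% ± 1.01) completed the set. Under quantile normalization the number adjusted over the list alone was 0 for T cell markers, 1 for the cell cycle and 0 for the respiratory chain, and it stayed 1 for the transcription factors, ILC1 and NK markers, housekeeping genes and glycolysis.

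As groups, none of the 30 lists passed camera's adjusted threshold for added succinate. ILC3 markers had the smallest p: 8 of 9 genes were higher, with a median change of 1.75 points (p = 0.00879, adjusted p = 0.264, and p = 0.169 with an estimated correlation). The result depended on single libraries: the adjusted p was 0.0323 without FK866 plus succinate 1 (0.850 with an estimated correlation) and 0.5003 without FK866 plus succinate 2. Lipid metabolism genes were narrower at 17 of 20 genes, with a median of -2.26 points (p = 0.0417, adjusted p = 0.417, and p = 0.165 with an estimated correlation). The ILC2 cytokine list averaged 50.8% ± 1.58 in FK866 and 50.7% ± 0.537 in FK866 plus succinate over the 11 members with any peak. Over the 10 tested members the median change was -1.59 points and the mean change -0.378 (adjusted p = 0.644), although camera placed them above the other genes. The ILC2 transcription factors averaged 59.1% ± 0.0320 and 56.6% ± 2.96, with a median change of 0.0313 points and a mean change of -2.49 (adjusted p = 0.803). TCA cycle genes were narrower at 18 of 23 (41.4% ± 0.678 and 38.7% ± 0.185, adjusted p = 0.417) and respiratory chain genes at 30 of 34 (40.4% ± 0.438 and 38.1% ± 0.137, adjusted p = 0.417). The median changes were -2.74 points for the TCA cycle and -1.875 for the respiratory chain, against -1.54 for all windows, and under quantile normalization -0.731 and 0.157 against 0.329. T cell markers were narrower at 6 of 10 genes (adjusted p = 0.803).

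Comparing FK866 plus succinate with Control covers both additions together. It uses the same 2 succinate libraries and the same pooled spread as the comparison with FK866. Overlap between these comparisons, here or in the sections below, is therefore not an independent result. Ifi206 was again the gained window with the strongest peaks, followed by Fsd1 (26.6% ± 4.81 in FK866 plus succinate, SD, n = 2), Ifne, which encodes interferon epsilon (17.6% ± 1.59), Trim6, a ubiquitin ligase gene of antiviral signalling (20.9% ± 3.32), Phf11a (7.55% ± 1.03), Npsr1 (7.74% ± 0.230), the interferon-inducible GTPase gene Tgtp1 (17.2% ± 1.54) and the lysophosphatidic acid receptor gene Lpar4 (16.0% ± 1.47). All 8 were at 0% in both Control libraries, and Ifi206, Ifne, Trim6, Phf11a and Tgtp1 were at 0% in both FK866 libraries as well. Itgam, a myeloid integrin gene, was gained among the B cell and myeloid markers (9.28% ± 0.849), through weak peaks with a mean -log10 p percentile of 29.1.

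Windows covered in Control and empty in both FK866 plus succinate libraries included Zbtb16 (19.9% ± 0.389 in Control, SD, n = 2), Wnt7a (28.3% ± 3.08), the neurotrophin receptor gene Ntrk3 (28.7% ± 12.1), Crtac1 (26.3% ± 22.8), Zfp385b (21.4% ± 0.725), Fcamr, an Fc receptor gene (13.0% ± 0.283), Banf2 (11.7% ± 5.53) and Ggt7 (8.90% ± 1.73). List members lost were the cytotoxic effector gene Prf1, which encodes perforin (17.7% ± 3.82), and the developmental genes Foxa2 (21.3% ± 3.13) and Hoxc8 (15.4% ± 1.43).

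In all, 156 windows were lost and 81 gained, a sum of 237 against 115 and 173 for the other splits. The region counts were 2088 lost and 2470 gained, a sum of 4558 against 3801 and 4297. With lists of equal length 2182 regions were lost and 1471 gained, with an adjusted p under 0.05 the values were 1383 and 498, and with the higher-scoring 50% of each list 439 and 730. The widest gained regions were those at Ranbp10 and Fsd1 and chr1:58409416-58411326, 662 bp from Clk1, and the widest lost were those at Scamp4 and Psd4 and chr5:118065973-118067959 inside Fbxw8. Regions lost and gained became 8108 and 4398 without Control 1, 14806 and 3771 without Control 2, 3921 and 21216 without FK866 plus succinate 1, and 4027 and 11794 without FK866 plus succinate 2. For windows the values were 240 and 251, 418 and 163, 297 and 432, and 336 and 195 in the same order.

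Limma called 0 of 15115 genes against Control, with a smallest adjusted p of 0.0715 and a median change of -1.58 points. At an unadjusted p under 0.05 there were 2096 genes, 257 wider and 1839 narrower, against 538 and 601 in the other splits. Quantile normalization gave a median of 0.452 points and 1626 genes, 742 wider and 884 narrower. Windows within 1 kb of the site gave 14 called genes, all narrower, of which 13 were also called against FK866. Many of the 14 were covered by 100% in both Control libraries and could not be wider, and some shared a window with a neighbour. Peaks with an adjusted p under 0.05 gave 9, of which 1 was wider and 8 narrower, and 7 of these were also called against FK866.

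Adjusted over the list alone, the passing genes were again all narrower with FK866 plus succinate. The anti-inflammatory cytokine gene Il10 had 98.0% ± 2.32 in Control, 91.0% ± 1.59 in FK866 and 87.4% ± 0.866 in FK866 plus succinate (SD, n = 2, adjusted p = 0.0188), and Zbtb16 and Eomes passed as before. Of the 29 cell cycle genes 6 passed, namely Ccna2, E2f2, Mcm3, Birc5, the replication clamp gene Pcna (51.9% ± 5.90 in Control and 38.8% ± 2.56 in FK866 plus succinate) and the mitotic transcription factor gene Foxm1 (57.1% ± 1.84 and 50.3% ± 1.03). Rpl13a, Gpi1, Cox7c, the enolase gene Eno3 (96.7% ± 1.72 and 84.6% ± 2.69), Uqcrfs1 of respiratory complex III (38.3% ± 0.247 and 30.1% ± 1.15), the mitochondrial helicase gene Twnk (46.9% ± 0.884 and 40.2% ± 0.442) and the histone demethylase gene Kdm5c (48.5% ± 0.0180 and 41.7% ± 0.636) passed too. Under quantile normalization the number for the cell cycle stayed at 6, and that for the ILC2 cytokines, respiratory chain, mitochondrial biogenesis and demethylase lists was 0.

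As in the other comparisons, none of the 30 lists passed camera's adjusted threshold. ILC3 markers were higher at 6 of 9 genes (median 1.76 points, p = 0.00684, adjusted p = 0.205, and p = 0.159 with an estimated correlation), with an adjusted p of 0.0124 without Control 1 (0.872 with an estimated correlation), 0.747 without Control 2, 0.0108 without FK866 plus succinate 1 (0.932 with an estimated correlation) and 0.513 without FK866 plus succinate 2. ILC2 receptors were higher at 11 of 20 genes (53.4% ± 0.841 in Control and 54.1% ± 0.864 in FK866 plus succinate, p = 0.0224, adjusted p = 0.298, and p = 0.114 with an estimated correlation). Cell cycle genes were lower at 23 of 29 (51.9% ± 0.230 and 48.1% ± 0.843, p = 0.0298, adjusted p = 0.298, and p = 0.242 with an estimated correlation), and under quantile normalization at 16 of 29. ILC1 and NK markers averaged 35.2% ± 2.17 in Control, 30.3% ± 0.324 in FK866 and 28.4% ± 5.38 in FK866 plus succinate (adjusted p = 0.645 against Control). NAD synthesis and recycling genes averaged 38.0% ± 1.05, 38.0% ± 0.206 and 35.6% ± 0.0566, and were lower at 16 of 20 with FK866 plus succinate against Control (adjusted p = 0.994) and, under quantile normalization, at 9 of 20.

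**Figure D3:**
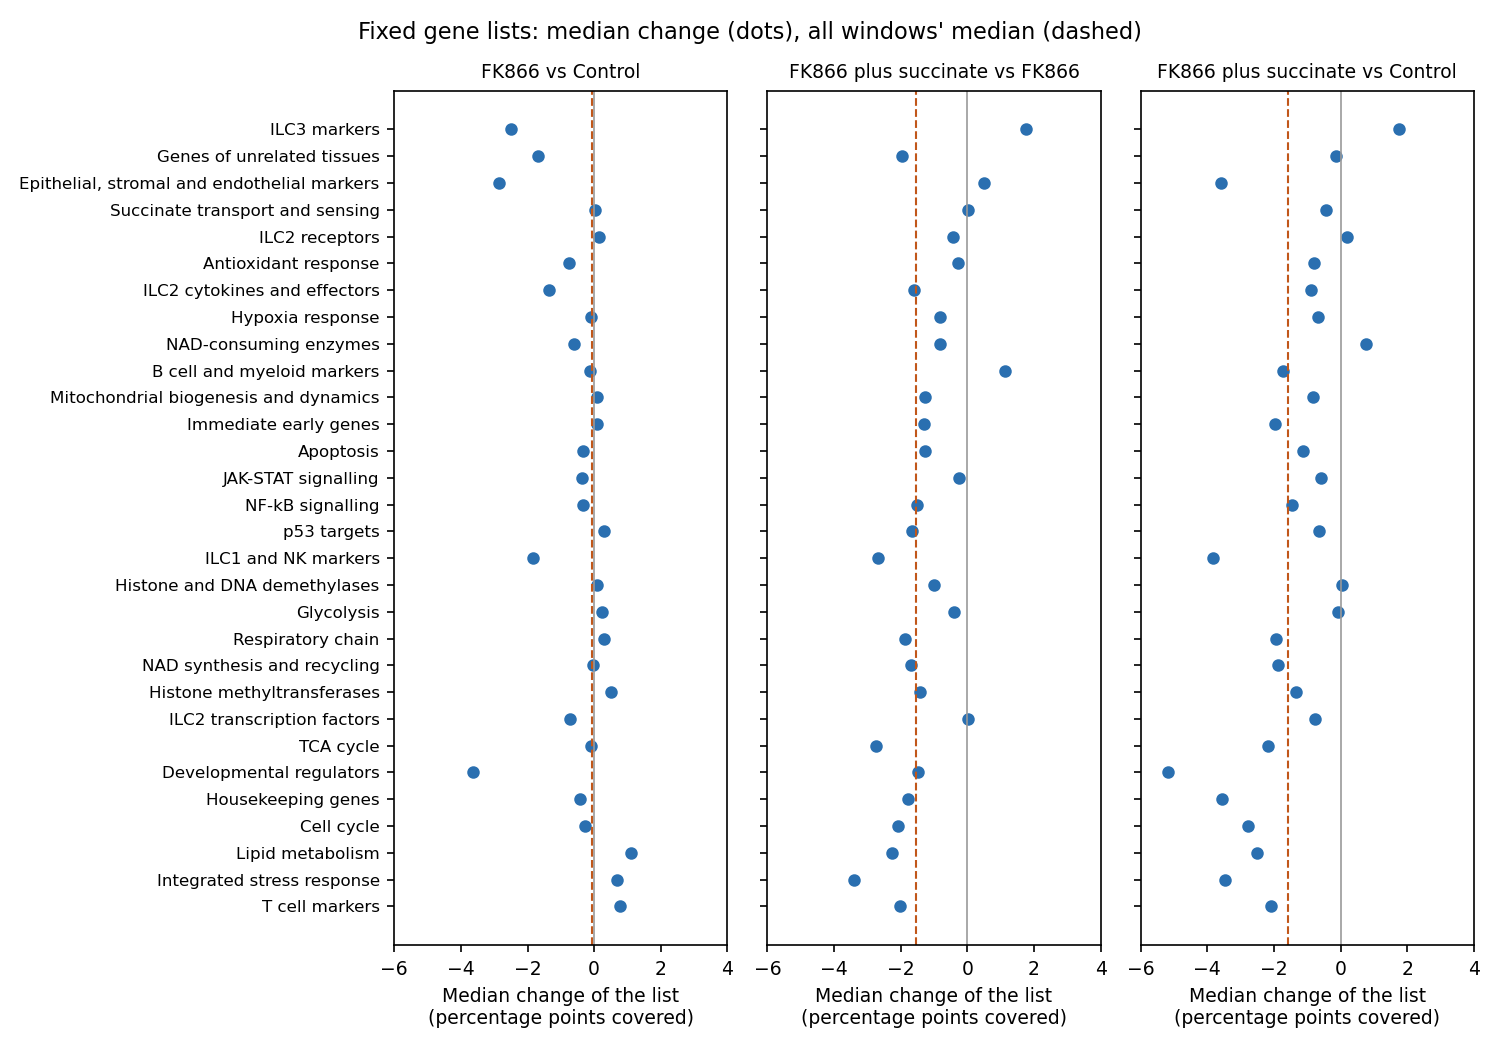
Median change in window coverage (percentage points, no scaling between libraries) of the 30 fixed gene lists in the 3 comparisons; dots are lists, the solid line marks 0 and the dashed line the median of all windows. With FK866 plus succinate the dashed line lies at -1.54 points against FK866 and -1.58 against Control, and under quantile normalization these medians are 0.329 and 0.452.

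A further question is whether peaks absent with FK866 return with succinate. There were 379 regions with a peak in both Control and both FK866 plus succinate libraries and in neither FK866 library. The same pattern with FK866 plus succinate as the group without peaks gave 487 regions, and with Control as that group 238. Over all 15 pairs of libraries taken as the pair without peaks, the FK866 pair came behind the FK866 plus succinate pair and a pair of 1 Control and 1 FK866 library (382 regions). The Tra2b and Padi1 regions, and the windows of Tslp and Gpx8, were among those with this pattern. The order of the groups depended on the peaks and libraries used. With FK866 and with FK866 plus succinate as the group without peaks, the counts were 211 and 624 with lists of equal length, 80 and 476 with an adjusted p under 0.05, and 168 and 131 with the higher-scoring 50% of each list. With 1 library left out they were 742 and 740 without Control 1, where Control itself gave 837, 977 and 845 without Control 2, 1119 and 827 without FK866 1, 921 and 869 without FK866 2, 837 and 1340 without FK866 plus succinate 1, and 735 and 1308 without FK866 plus succinate 2.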

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

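The tests at an adjusted p under 0.05 and at gene ends only were chosen after the results were seen. The other alternatives were planned, but not for every result. For the gene lists, equal list length, windows within 1 kb and leaving out single libraries were not planned. For regions without peaks only in FK866, the higher-scoring 50% and merging within 500 bp were not planned. Of the 92 values that moved, most were counts of lost or gained regions and windows, and the cause was not tested except where the alternative itself makes lists shorter or the rule looser. The higher-scoring 50% of each list gave 503 regions lost and 151 gained for FK866 against Control, 266 and 1073 for FK866 plus succinate against FK866, 439 and 730 against Control, and 168 regions without peaks only in FK866. Lists of equal length gave 1504 and 1471 regions gained with FK866 plus succinate against FK866 and Control, 211 regions without peaks only in FK866, 52 windows gained with FK866 and 157 windows lost with added succinate. With peaks covering 50% of a region, 211 regions were without peaks only in FK866. Merging within 500 bp moved no count by more than 1.5 times.

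Peaks with an adjusted p under 0.05 gave 696 regions lost and 635 gained for FK866 against Control, 504 gained for FK866 plus succinate against FK866, 1383 lost and 498 gained against Control, and 80 without peaks only in FK866. Windows became 70 lost with FK866, 186 lost and 56 gained with added succinate, and 40 gained against Control, and coverage calls became 16 and 9. Presence at an adjusted p under 0.05 with absence at any p gave regions of 241 lost and 160 gained, 306 and 195, and 364 and 158, with 21 without peaks only in FK866, and windows of 19 and 7, 40 and 20, and 65 and 8. Windows within 1 kb gave 28 and 14 coverage calls and 26.4% of peaks near a gene end. With windows at gene ends only, 2 lists passed for added succinate, ILC2 receptors and ILC3 markers, each with an adjusted p of 0.0357 at the preset correlation and 0.570 with an estimated one, a check added after the results were seen; over the other alternatives the adjusted p of ILC3 markers lay between 0.0323 and 0.712.

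With each library left out in turn, a lone sample is assumed to vary like the other groups. Regions lost and gained then ranged from 2072 to 15976 and 1420 to 10126 for FK866 against Control, 1705 to 10242 and 2799 to 22475 for FK866 plus succinate against FK866, and 2088 to 14806 and 2470 to 21216 against Control, and those without peaks only in FK866 from 735 to 1119. Windows ranged from 111 to 470 and 33 to 163, 102 to 250 and 129 to 549, and 156 to 418 and 81 to 432. Coverage calls stayed between 0 and 0 in limma, and lists past the threshold between 0 and 1 in both succinate comparisons, with ILC3 markers the list that passed, and in those cases it did not pass with an estimated correlation.

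Libraries of different groups with the same replicate number were not more alike, with a mean Jaccard index that differed from the others by -0.00204. The labels do not say what the numbers stand for. So few indices cannot exclude that number-matched libraries share a culture or animal. With the replicate number as a block limma called 0 genes, with 744, 1948 and 1964 at an unadjusted p under 0.05. The most upstream transcript start of each gene was planned and not run, since the gene table has no strand or transcripts.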

Other observations

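The tests of the interferon-stimulated, class I antigen presentation and ribosomal protein lists, and those of the explanations weighed here, were chosen only after the window results were seen. Interferon-stimulated genes, which cells switch on in response to type I interferon, had wider windows with FK866 plus succinate. Of 36 measured genes 30 were higher than with FK866, with a median change of 3.06 points against -1.54 for all windows (camera p = 1.39e-16, and p = 0.0138 with an estimated correlation). The antiviral gene Rtp4 had 50.8% and 51.0% of its window covered with added succinate and 14.8% and 0% with FK866. Ifit1 had 36.2% and 52.1% against 8.15% and 10.2%, Oas3, which senses double-stranded RNA, 62.4% and 61.0% against 36.5% and 43.9%, Rsad2, which encodes viperin, 37.1% and 39.2% against 20.6% and 13.3%, and Irf9, part of the interferon-activated ISGF3 complex, 50.3% and 47.2% against 37.4% and 39.0%. Usp18 had 23.2% and 25.02% against 28.2% and 29.7%, and was not wider. When adjusted over the list alone 10 genes passed in limma and over all genes 0, and the former is not independent evidence, since Trim30a, Trim12a and Ifi206 prompted the list. Against Control 28 of 36 genes were higher (median 1.68 points, p = 1.84e-15, and p = 0.0154 with an estimated correlation), while FK866 against Control gave p = 0.704. Without FK866 plus succinate 1 the median change against FK866 was 0.638 points, with 21 of 35 genes higher (p = 1.32e-08, and p = 0.0223 with an estimated correlation). Against FK866 the p with an estimated correlation lay between 0.0492 and 0.0582 without any 1 Control or FK866 library, and between 0.0664 and 0.0858 when the prompting genes were left out too. Against Control these p values lay between 0.0509 and 0.0739, and between 0.0767 and 0.108 without the prompting genes, so the call at an estimated correlation depends on single libraries. The Ifi200, Trim30 and Oas genes are families of close paralogs, so their single values are uncertain.

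Ribosomal protein genes went the other way: 68 of 77 windows were narrower than with FK866 (median -2.58 points, p = 2.20e-04, and p = 0.0163 with an estimated correlation) and 70 of 77 narrower than in Control (median -3.96 points, p = 4.78e-07, and p = 0.00686 with an estimated correlation). Rpl3 had 72.0% ± 0.336 in Control, 71.9% ± 0.159 in FK866 and 52.2% ± 1.06 in FK866 plus succinate (SD, n = 2, adjusted p = 0.0777 in limma). Under quantile normalization 44 and 51 of 77 were narrower, with p values of 0.0340 and 6.69e-05, and of 0.0673 and 0.0132 with an estimated correlation. With windows within 1 kb of the site the list lay above the other genes, with p values of 0.477 and 0.480. Without any 1 FK866 or FK866 plus succinate library the p against FK866 with an estimated correlation lay between 0.0517 and 0.0598, so that call depends on single libraries, while against Control it lay between 0.0237 and 0.0317 without any 1 of the 6. Part of the narrowing goes with coverage: against the other 4 libraries the list shifted by -3.99 points, and 10000 random lists matched on coverage by -2.49 on average, 14 of them as far or further. Windows of class I antigen presentation genes did not stand apart, with 5 of 13 higher than with FK866 (p = 0.676, and p = 0.722 with an estimated correlation).

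The wider interferon-stimulated windows were weighed against 3 technical explanations. Longer lists could add peaks to thinly covered windows, but the mean shift of the list was 7.83 points, above the highest of 10000 random lists matched on coverage (1.41 points). This includes Trim30a, Trim12a and Ifi206. The other 33 genes shifted by 6.52 points, above a highest of 1.23 for their matched lists, with a camera p of 0.0210 with an estimated correlation. Those 3 genes alone therefore do not carry the shift. The other 33 were still listed after the window tests were seen. They include Rtp4 and Oas3, which were also among the wider genes with the smallest limma p, so these values are not independent evidence. B cells or myeloid cells might bring such genes, and sorting should remove them; their 9 measured markers had a median change of 1.14 points (spread 5.36, 5 of 9 higher) but a mean change of -0.797 (p = 0.248, and p = 0.316 with an estimated correlation), and the most covered, Cebpa (38.9% and 40.8% with added succinate, 45.6% and 41.5% with FK866) and Cd68 (40.3% and 35.6%, 40.4% and 44.5%), were not wider, which leaves this open. For succinate itself, the pair of succinate libraries shifted by 9.69 points against the other 4, relative to all windows (8.39 without the prompting genes). The largest of any other pair in size was -5.42 points, for Control 2 and FK866 2. Every other pair has a succinate library among the 4 it is set against, so its value carries part of the same shift. The other pairs are thus no measure of chance spread, and 15 pairs allow no share below 0.0667. A response of the cells to succinate remains a hypothesis that these values do not settle, and a culture or library batch that coincides with the group cannot be told apart from it.

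The narrower windows with added succinate were weighed against depth and enrichment. Lower depth would make windows of the shallower library of each group narrower as well. The deeper library minus the shallower was -0.0149 points on average over the 3 groups (SD 0.118), against 1.70 points between the FK866 and the FK866 plus succinate libraries. The gap in background was 0.433 within groups and 0.359 between these groups. Median peak width, over all listed peaks, did go with depth. The shallower and deeper libraries had 616 and 723 bp in Control, 651 and 737 bp in FK866, and 528 and 618 bp in FK866 plus succinate. Group means were 694 bp in FK866 and 573 bp in FK866 plus succinate. The window values thus speak only to mean window coverage, and an effect of depth on peak width is not excluded. Weaker enrichment in the succinate libraries might narrow their peaks: their number of peaks with an adjusted p under 0.05 differed from that of FK866 by -1542, with a spread of 1178. The second succinate library (26853) lay close to the second FK866 library (26872), which leaves this open, and enrichment cannot be told apart from a treatment effect with 2 libraries per group.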
